A study of Homo sapiens with 12 samples.

How the data were processed

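The sources used here were the labels of 12 libraries, the series' design text, the submitters' processing notes and 2 peak lists, 1 per protein. Per the labels, U2OS cells with a tet-on transgene for Flag-tagged REXO4-D386A or RNaseH1-D210N were grown with or without doxycycline, fixed with formaldehyde and precipitated with anti-Flag beads, with input libraries beside them. Per the submitters' processing notes, the tools were Trim Galore 0.6.10, HISAT2 2.2.1, Cufflinks, SAMtools 1.17, deepTools 3.5.1 and MACS2 2.1.0.20150731, and the build was hg38. The Cufflinks version and what Cufflinks was used for are not given in the sources used here. The control, the libraries entered, the pooling of replicates and the threshold for peak calling are likewise not given in the sources used here. The peak names of both lists carry the label ChIPseq2, and whether this stands for replicate 2 is not known, so each list may rest on a single replicate. The largest q was 0.179 in the REXO4 list and 0.198 in the RNaseH1 list.

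The fold enrichment of each peak is the authors' deposited value, and the peak caller was MACS2, per the submitters' processing notes. It was read here as the ratio of fragments at the summit to the expected pileup, each with 1 added. The −log10 p and −log10 q of each peak are the authors' values from the same caller, as deposited. Fold enrichment was used only to describe, rank and compare peaks within a list, never between the lists. Peak scores were not used.

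All else was computed here from the peak positions and these values. A peak's fragments and expected pileup were recovered as the whole number of fragments whose Poisson tail gives the peak's p at its fold, with a tolerance of 0.05 fragments. This gave whole numbers for 1459 of 1460 REXO4 peaks (99.9%) and for all 54623 RNaseH1 peaks. The 95% intervals of folds are exact Poisson intervals of the fragments, cover counting error only, and leave out variation between libraries. This recovery was chosen after the values were seen.

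Genes came from a table of 59792 genes, of which 58994 were kept and 798 left out because they had no position or stood out of order on their chromosome, as genes on scaffolds do. The table gives no strand, so the planned distance to gene starts became the distance to either gene boundary. A summit within 1 kb of either boundary of a protein-coding or lncRNA gene was near it. A gene counted as having a peak when a peak overlapped the 1 kb on either side of 1 of its boundaries. Genome sequence was not used here, so tests on GC content and soft-masked repeats were not run, nor were tests on all transcript starts.

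An overlap was at least 1 bp. Random positions kept each peak's width and chromosome, with 10000 draws for REXO4 and 1000 for RNaseH1, and permutation p-values are two-sided. Assembly gaps were approximated: positions ran from the first to the last gene of a chromosome and left out stretches of over 3 Mb without a gene. Folds of shared and other peaks were compared by 100000 resamples of the labels. Within bins, the mean of shared peaks was compared with that of all peaks of the same bins. Gene lists were compared with the other genes of their class by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 17 lists. Intervals of shares are exact binomial intervals. Neighbouring peaks are not independent, and these intervals and tests treat them as if they were.

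Genes were named by a rule fixed before the data were examined. It took the 12 genes of highest fold in each list, the 10 overlapping pairs ranked best in both lists, up to 4 members per fixed list and the 2 genes that the transgenes copy. Some members of fixed lists that the rule selects are not reported here. Members of fixed lists without a peak and other peaks by position were named after the values were seen. rDNA-bearing sequence meant chromosome 21 below 9 Mb, 2 scaffolds that carry rDNA, and peaks at annotated rRNA genes. The narrower count, within 45 kb of a 45S gene in place of the limit of 9 Mb, was added after the values were seen.

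The overlap, gene list and fold tests and the recovery of fragments were run on simulated data first, and the other tests were not simulated. With peaks placed by the same random rule as in the test, 2% of 100 simulations gave an overlap p under 0.05. With 30% of 1380 peaks moved onto RNaseH1 peaks, the estimate was 30.3%. With peaks given to genes independently and at random, 3.35% of tests over 17 lists gave p under 0.05. This leaves out neighbouring genes that share a peak. With 80% of the 78 ribosomal protein genes given a peak, the estimate was 76.9% and 1 list was called. Random labels gave p under 0.05 in 5% of fold tests over 1380 peaks. A log2 shift of 0.5 moved the estimate from -0.07 to 0.43. Fragments were recovered for 100% of 999 simulated peaks. The software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.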

Results

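Flag ChIP-seq was made from U2OS cells, a human osteosarcoma line, carrying a doxycycline-inducible transgene for a nuclease-dead protein. In 1 line the protein was REXO4-D386A, a mutant of a protein of the RNA exonuclease family. In the other it was RNaseH1-D210N, a mutant of the enzyme that degrades the RNA strand of RNA:DNA hybrids. The question was whether these proteins bind R-loops, structures in which RNA pairs with a DNA strand and displaces the other strand. The labels describe 12 libraries, 6 per line, falling into 8 groups. Each line was grown with or without doxycycline at 1 µg/ml for about 60 h, and each of these conditions had 2 ChIP libraries and 1 input library. The values analysed here were 2 peak lists, 1 per protein, in hg38 coordinates. Whether a list rests on 1 or both replicates is not given in the sources used here. No value per library was analysed, so none of the comparisons has a replicate error, and the p-values below describe these lists of peaks. Peaks without doxycycline were not analysed here.

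The REXO4 list held 1460 peaks and the RNaseH1 list 54623, which is 37.4 times as many. The authors' fold enrichment had a median of 2.30 for REXO4 (interquartile range 1.89 to 3.08) and 3.07 for RNaseH1 (2.64 to 3.60). The median peak was 352.5 bp wide in the REXO4 list and 365 bp wide in the RNaseH1 list. A median REXO4 peak rested on 80 fragments at its summit against an expected 36.6. A median RNaseH1 peak rested on 23 fragments against an expected 7.14. These fragment numbers were recovered from each peak's fold enrichment and p-value and give the counting error behind each fold.

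Most REXO4 peaks overlapped RNaseH1 peaks. Of the 1460 REXO4 peaks, 1044 overlapped an RNaseH1 peak by at least 1 bp, 71.5% (95% exact interval 69.1 to 73.8). REXO4-sized regions placed at random on the same chromosomes overlapped in 2.85% of cases (95% range of the draws 2.05 to 3.70), a 25.1-fold difference (permutation p = 0.0002, two-sided, the smallest that 10000 draws can give). The summits of shared peaks were a median of 109 bp apart (interquartile range 38.8 to 234), and 738 of the 1044 shared REXO4 peaks (70.7%) had a summit within 200 bp of an RNaseH1 summit. Seen from the other list, 1107 of 54623 RNaseH1 peaks (2.03%) overlapped a REXO4 peak. At the level of genes, 758 protein-coding genes had a REXO4 peak within 1 kb of a gene boundary, and 693 of them (91.4%) also had an RNaseH1 peak at a boundary, against 67.1% of all 19862 protein-coding genes (odds ratio 5.45, Fisher's exact p = 2.18e-58). For lncRNA genes it was 199 of 227 (87.7%) against 27.2% (odds ratio 19.8, Fisher's exact p = 1.29e-82). Random positions in the same annotation class overlapped in 8.80% of cases, which lowered the difference to 8.13-fold. With the RNaseH1 list reduced to its 1460 peaks of highest fold, 69 REXO4 peaks overlapped (4.73%, random 0.181%). With its 1460 peaks of lowest q, 153 did (10.5%, random 0.601%).

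Shared REXO4 peaks were the weaker part of the REXO4 list by fold and the deeper part by coverage. Their median fold was 2.05 against 3.35 for the 416 unshared peaks, a difference of -0.60 in mean log2 fold (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give). The expected pileup at shared peaks was 51.5 fragments, and that at unshared peaks 6.37. With the list split into 5 bins by fold, 94.9% of the bin of lowest fold overlapped an RNaseH1 peak (95% exact interval 91.7 to 97.1). In the bin of highest fold, 30.1% did (24.9 to 35.8). By expected pileup the order turned: 16.4% of the lowest bin overlapped (12.4 to 21.2), and 97.9% of bin 4 of 5 did (95.6 to 99.2). In the highest bin, 91.4% did (87.6 to 94.4). Within bins of expected pileup, the mean log2 fold of shared peaks differed by -0.00271 from that of all peaks of the same bins (permutation p = 0.51). This is not the difference from unshared peaks, so its size cannot be set against -0.60. In the RNaseH1 list, peaks that overlapped a REXO4 peak had a median fold of 3.12 against 3.06 elsewhere, a difference of 0.02 in mean log2 fold that did not pass the test (permutation p = 0.053). They were wider, with a median of 866 bp against 361 bp. The direction of this small difference turned within bins of peak width. It was kept within bins of expected pileup, where shared peaks lay 0.0800 above all peaks of the same bins (permutation p = 1e-05).

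**Figure D1:**
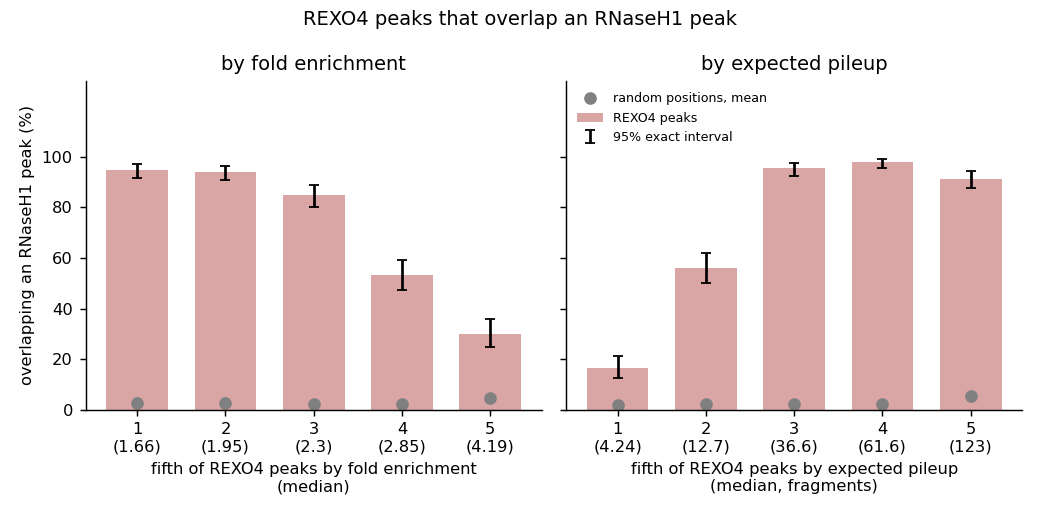
Share of REXO4 peaks that overlap an RNaseH1 peak (vertical axis, percent), with REXO4 peaks split into 5 bins by fold enrichment (left) or by expected pileup in fragments (right); bars are shares, error bars 95% exact intervals, grey points the mean of random positions. The share falls from 94.9% to 30.1% with rising fold. It rises from 16.4% to 97.9% between bins 1 and 4 of expected pileup and is 91.4% in bin 5.

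Ribosomal DNA held the most significant REXO4 peaks. All 30 REXO4 peaks with a −log10 q above 500 lay in rDNA-bearing sequence, had folds of 3.66 to 10.4 and overlapped RNaseH1 peaks. The highest −log10 q elsewhere in the REXO4 list was 87.9. On the short arm of chromosome 21, the 45S genes RNA45SN1 (8433222 to 8446572), RNA45SN2 (8205988 to 8219302) and RNA45SN3 (8389035 to 8402343), which encode the precursor of 18S, 5.8S and 28S rRNA, overlapped 9 REXO4 peaks with a median fold of 6.20 (4.18 to 8.26). A single REXO4 peak from 8432190 to 8447132 covered all of RNA45SN1 at a fold of 5.98 (95% interval 5.83 to 6.13, counting error only). The peak over 1 end of RNA45SN2, from 8205016 to 8209204, reached 8.26 (8.08 to 8.44) with 8402 fragments against an expected 1016. Under the naming rule this peak falls to MIR3648-1, a microRNA gene within 1 kb of its summit, and its copy MIR3648-2 had 8.18. The peaks that the rule names by RNA18SN2, RNA18SN3, RNA28SN3 and RNA45SN3 had folds of 6.71, 6.55, 6.49 and 6.20. A peak can span several genes: the first also covered RNA5-8SN2. The others all overlapped RNA45SN3, whose highest fold was thus 6.55. Between RNA45SN2 and RNA45SN3, the 18S and 5.8S pseudogenes RNA18SP5 and RNA5-8SP10 had REXO4 folds of 8.11 and 6.28. The RNaseH1 list held 16 peaks at the same 3 genes, with a median fold of 3.81 (3.07 to 5.61). In all, 92 REXO4 peaks (6.30%) and 205 RNaseH1 peaks (0.375%) were in rDNA-bearing sequence (odds ratio 17.9, Fisher's exact adjusted p = 1.30e-70 over 6 position classes). Over all 92 the median REXO4 fold was 2.13, below the 2.30 of the whole list, so high folds did not extend over the whole class. This class takes the whole arm of chromosome 21 below 9 Mb, which holds other sequence too. Counted within 45 kb of the 45S genes, at other rRNA genes and on rDNA scaffolds only, it held 89 REXO4 and 154 RNaseH1 peaks (odds ratio 22.96, Fisher's exact p = 1.72e-76). Both odds ratios compare lists of unlike length. Among the 500 peaks of lowest q in each list, 80 REXO4 and 78 RNaseH1 peaks were in rDNA-bearing sequence. Among the 500 of highest fold, 36 and 15 were. The 45S genes occur in many near-identical copies of which the assembly holds few, so the fragments at 1 position come from many copies.

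**Figure D2:**
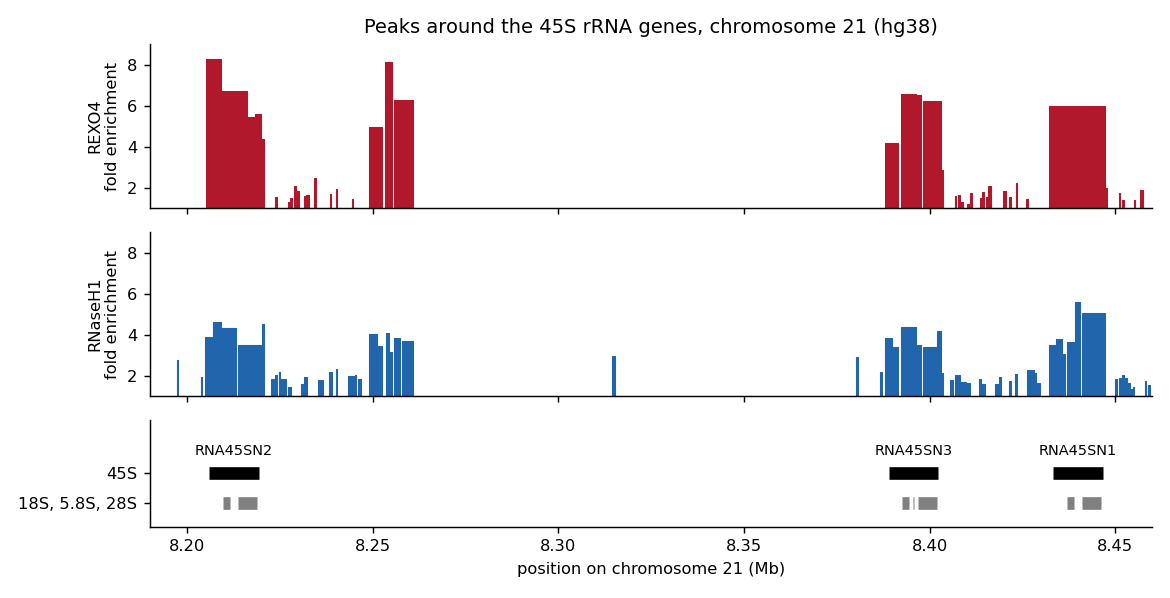
Peaks around the 45S genes on the short arm of chromosome 21 (horizontal axis, Mb, hg38), drawn as boxes from peak start to peak end with the peak's fold enrichment as height, for REXO4 (top) and RNaseH1 (middle); in the lowest part black bars are the 45S genes and grey bars the 18S, 5.8S and 28S genes. REXO4 peaks of 4.18 to 8.26 span the 3 named 45S genes.

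By fold, the RNaseH1 list was led by tRNA genes. Of its 100 peaks of highest fold, 75 had a summit within 1 kb of a tRNA gene and 0 lay in rDNA-bearing sequence. Of its 100 peaks of lowest q, 45 were at a tRNA gene and 43 in rDNA-bearing sequence. Of all 54623 peaks, 303 (0.555%) had a summit within 1 kb of a tRNA gene. Those 303 peaks had a median fold of 8.86 (interquartile range 4.59 to 14.8), at a median percentile of 99.6 in the list. Of 429 tRNA genes on assembled chromosomes, 345 (80.4%) had an RNaseH1 peak, against 25.9% of other noncoding genes (odds ratio 11.7, Fisher's exact adjusted p = 6.91e-120 over 8 gene classes). The genes with the highest folds had such neighbours. RAB11A, a GTPase of recycling endosomes on chromosome 15, had a fold of 40.1 (95% interval 37.3 to 43.1, counting error only) at 65868708 to 65870439, beside TRQ-CTG1-4. The peak at HES7, a segmentation clock repressor, had 36.6, with TRL-TAG1-1 and TRR-TCT2-1 within 1 kb of its summit. The peaks at ZNF839 (31.6) and LINC01623 (29.2) each lay by a tRNA gene. Peaks at TRD-GTC2-10, TRK-CTT1-1, TRF-GAA1-4, TRP-AGG2-4, TRK-TTT3-1 and TRL-TAG3-1 had folds of 38.7, 38.2, 32.5, 31.3, 30.04 and 27.9. Among the 12 genes named for the highest RNaseH1 folds, only JUND, an AP-1 subunit (31.1, 29.6 to 32.8), and ERRFI1, a feedback inhibitor of EGF receptor signalling (28.7, 27.1 to 30.3), had no tRNA gene within 1 kb of the summit. None of these 12 peaks overlapped a REXO4 peak, but only 2.03% of all RNaseH1 peaks and 1.98% of those at tRNA genes did. The absence among 12 peaks therefore says little. REXO4 peaks lay at 20 tRNA genes, all with an RNaseH1 peak too, and 19 of them were in a cluster on chromosome 1 between 161440171 and 161471205. By summit, 11 REXO4 peaks (0.753%) were within 1 kb of a tRNA gene. This share did not differ detectably from the 0.555% of RNaseH1 peaks (odds ratio 1.36, Fisher's exact adjusted p = 0.285). Their median fold was 2.23, near the 2.30 of the REXO4 list. By q they ranked high, with 10 of them among the 100 REXO4 peaks of lowest q. The 186 tRNA genes with an RNaseH1 fold of 10 or more had 0 REXO4 peaks, and the highest RNaseH1 fold at a tRNA gene with one was 8.25.

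**Figure D3:**
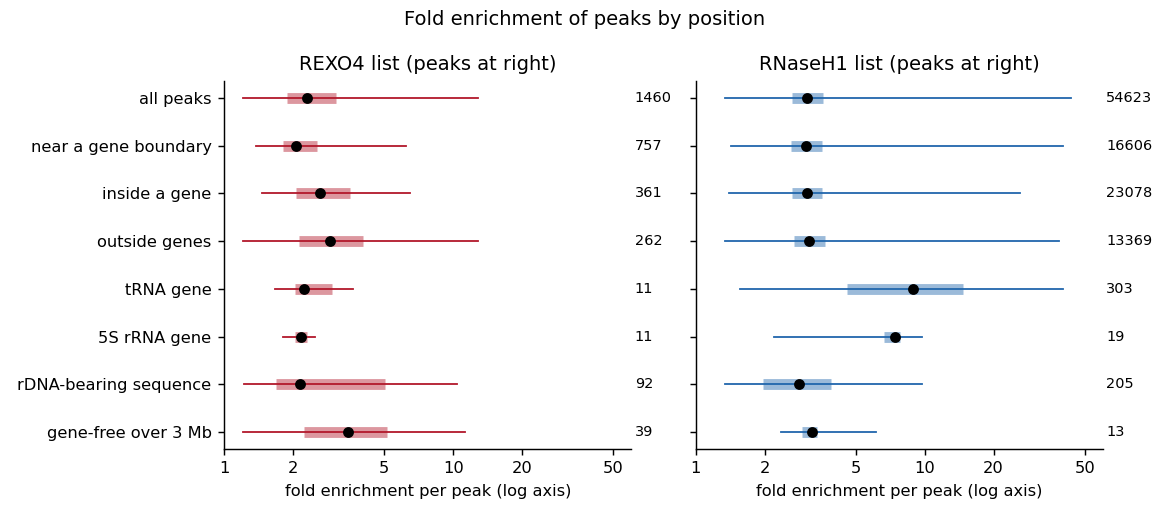
Fold enrichment per peak (horizontal log axis) by the position of the peak (vertical axis), for the REXO4 list (left) and the RNaseH1 list (right); dots are medians, thick bars interquartile ranges, thin lines minimum to maximum, and the number of peaks stands at the right. Folds are comparable only within a list: tRNA gene peaks have a median of 8.86 against 3.07 for all RNaseH1 peaks, and REXO4 peaks in gene-free stretches 3.49 against 2.30 for all REXO4 peaks.

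Outside rDNA, the strongest REXO4 peaks by fold were mostly not in RNaseH1 peaks. The highest fold of the list was 12.8 on chromosome 14, from 17160276 to 17160601, outside annotated genes, with 39 fragments against an expected 2.12. Stretches of over 3 Mb without an annotated gene held 39 REXO4 peaks (2.67%) and 13 RNaseH1 peaks (0.0238%), an odds ratio of 115 (Fisher's exact adjusted p = 8.94e-51). Of these 39 peaks, 13 lay on chromosome 1 between 121571889 and 143299517, 7 on chromosome 17 and 7 on chromosome 19. A single peak of the 39 was shared with RNaseH1. The peak on chromosome 17 from 25965427 to 25965721 had a fold of 11.3, at the lowest expected pileup of the REXO4 list. Within genes, the highest REXO4 folds outside rDNA were at XRCC1, a scaffold of DNA single-strand break repair (6.48, 95% interval 4.44 to 9.17, counting error only, 30 fragments), at SNRPN, an imprinted gene (6.29, 4.05 to 9.39), and at CTNNA2, a neuronal catenin (6.24, 4.16 to 9.03). All 3 peaks were inside the gene and none overlapped an RNaseH1 peak. The summit in CTNNA2 also lay within 1 kb of a boundary of another protein-coding or lncRNA gene. The expected pileups of the 3 peaks were low too, at 3.78, 2.65 and 3.33 against a median of 36.6 for the list. Among the 10 overlapping pairs that ranked best in both lists, 7 were in rDNA-bearing sequence. The others were a pair on chromosome 17 from 26534495 to 26534800 in a gene-free stretch, a pair on chromosome 19 from 56171870 to 56172170 outside genes, and a pair inside NARS2, a mitochondrial asparaginyl-tRNA synthetase (REXO4 fold 4.80, 2.77 to 7.84; RNaseH1 fold 5.03, 3.13 to 7.71).

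Peaks of both proteins gathered at gene boundaries. Of the REXO4 summits, 757 (51.8%, 95% exact interval 49.3 to 54.4) lay within 1 kb of either end of a protein-coding or lncRNA gene, 10.1 times the 5.14% of random positions (permutation p = 0.0002, two-sided, the smallest that 10000 draws can give). Of the RNaseH1 summits, 16606 (30.4%, 30.02 to 30.79) did, 5.83 times the random 5.22% (permutation p = 0.002, the smallest that 1000 draws can give). The REXO4 share was higher (odds ratio 2.47, Fisher's exact p = 2.98e-63). The order turned where only the 1460 RNaseH1 peaks of lowest q were compared: 65.1% of those lay at a boundary (odds ratio 0.576, Fisher's exact p = 3.85e-13). It held against the 1460 RNaseH1 peaks of highest fold, of which 33.2% did (odds ratio 2.16, Fisher's exact p = 2.52e-24). With peaks of both lists held to a q of 1e-05 or less, the shares were 55.1% and 50.3% (odds ratio 1.21, Fisher's exact p = 0.00975). The REXO4 share also varied with expected pileup, from 21.2% in the lowest of 5 bins to 77.4% in bin 4 and 53.1% in the highest. The annotation used gives no strand, so starts and ends of genes were not told apart.

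RNaseH1 peaks lay at nearly all housekeeping genes of the fixed lists, such as ribosomal protein and translation factor genes. They also lay at nearly all genes of the fixed list for spliceosomal, 7SK and 7SL RNAs. Of the 17 lists fixed before the data were examined, 12 differed from the other genes of their class in Fisher's exact test after Benjamini-Hochberg adjustment, 11 higher and 1 lower. Loci often used as R-loop reference sites had a peak at 14 of 15 genes (93.3% against 48.1% of other protein-coding and lncRNA genes, exact adjusted p = 0.000844). Examples were NEAT1 (7.84, 6.69 to 9.14), EGR1 (7.66, 6.59 to 8.86) and MALAT1 (5.86, 4.81 to 7.08), while TFPT had none. The background of this list pools protein-coding genes, 67.1% of which had a peak, with lncRNA genes, at 27.2%. Ribosomal protein genes (94.9%) and glycolysis genes (94.1%) had a peak about as often, so the share is not particular to R-loop reference loci. No list was matched on expression. Among loci used as R-loop-poor sites, 1 of 4 had a peak (ZNF554, 3.38), which did not pass the test (exact adjusted p = 0.140). Cytosolic ribosomal protein genes had a peak at 74 of 78 genes (94.9% against 67.0%, exact adjusted p = 1.59e-08), with RPL31 at 5.04, RPS18 at 4.84 and RPL27A at 4.75. Immediate early genes had 23 of 24 (95.8%, exact adjusted p = 0.00248), with JUND at 31.1 and FOS at 6.35. Translation factors had 18 of 18 (exact adjusted p = 0.00248), such as EIF4G1 (4.12), EIF4A3 (4.08), EIF4A2 (3.88) and EIF3B (3.74). Glycolysis genes had 16 of 17 (exact adjusted p = 0.0251), such as PKM (4.39), ALDOC (4.18), PGK1 (3.54) and PFKM (3.16), though not with a window of 2500 bp (exact adjusted p = 0.0773). Nucleolar and ribosome biogenesis genes had 23 of 24 (exact adjusted p = 0.00248), such as WDR12 (4.82), UTP4 (4.25) and RRP1 (4.18).

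R-loop processing factors had an RNaseH1 peak at 30 of 30 genes (against 67.1%, exact adjusted p = 3.69e-05), among them the nuclease gene MRE11 (4.52). DNA replication genes had 28 of 30 (93.3%, exact adjusted p = 0.00248), with MCM10 at 5.12, POLA1 at 4.82, RPA1 at 4.52 and MCM6 at 4.31. The spliceosomal snRNA, 7SK and 7SL list had 35 of 37 (94.6% against 26.9% of other noncoding genes, exact adjusted p = 7.06e-17). RN7SL2 and RN7SL1, which encode the RNA of the signal recognition particle, had folds of 23.4 (21.8 to 25.1) and 17.1 (15.6 to 18.9). RN7SK, the RNA that holds the elongation factor P-TEFb, had 15.1 and RNU6-2 12.2. The snoRNA host and abundant lncRNA genes had 20 of 23 (87.0%, exact adjusted p = 1.59e-08), including GAS5 (4.71) and MEG3 (4.23), and the ribosomal RNA genes 23 of 23 (exact adjusted p = 6.79e-13). Genes of other tissues had fewer, 8 of 32 (25% against 67.2%, exact adjusted p = 4.31e-06), among them HBA1 (3.87) and APOA1 (3.40). Over whole gene bodies, against random lists matched on gene length, this list did not pass (53.1% against 68.5%, permutation adjusted p = 0.0942). Histone genes (42 of 57, exact adjusted p = 0.346), heat shock and chaperone genes (15 of 18, exact adjusted p = 0.253), common fragile site genes (13 of 20, exact adjusted p = 0.815) and osteoblast and mesenchymal genes (11 of 20, exact adjusted p = 0.276) did not pass. Histone genes did pass over gene bodies against length-matched lists (73.7% against 24.8%, permutation adjusted p = 0.000486). Members with a peak included H1-2 (8.35), H1-4 (8.02), H2BC12 (4.25), HSPA5 (5.36), BAG3 (4.02), HSP90AB1 (3.98), DNAJA1 (3.87), NAALADL2 (5.12), FN1 (4.32), COL1A1 (3.96), COL1A2 (3.80) and LGALS1 (3.65). At H4C8 (14.2) and CTNNA3 (17.6) the peak was also within 1 kb of a tRNA gene.

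**Figure D4:**
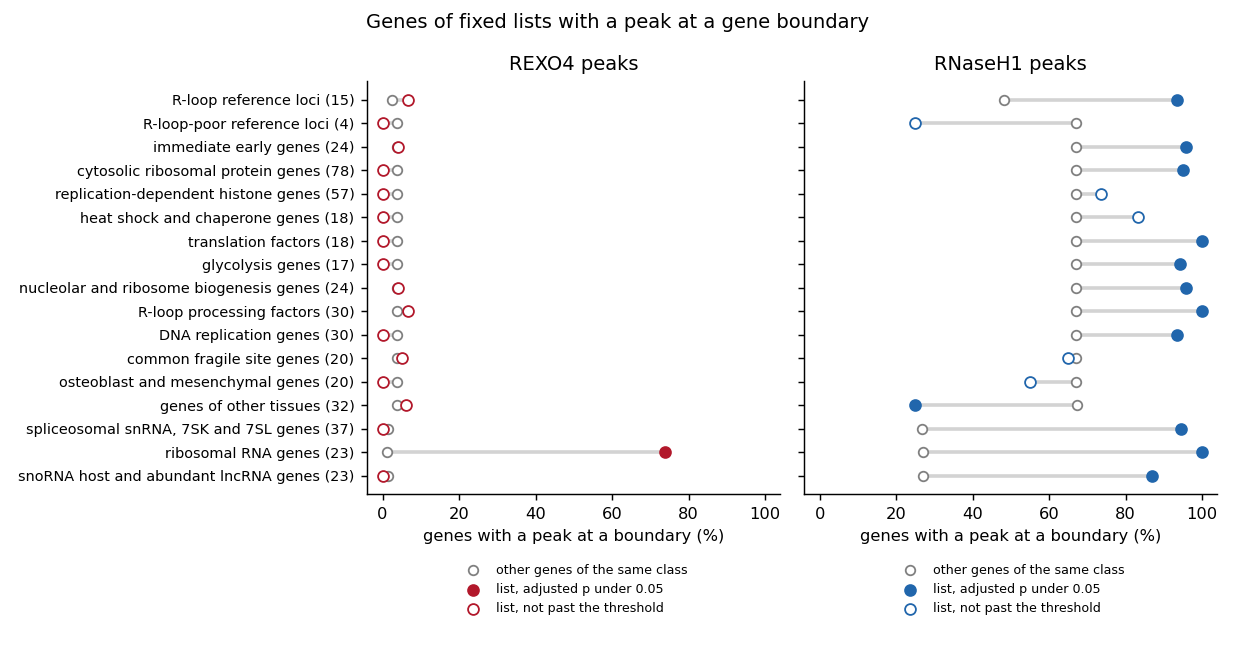
Share of genes with a peak within 1 kb of a gene boundary (horizontal axis, percent) for each of the 17 fixed lists (vertical axis, with the number of genes measured), for REXO4 peaks (left) and RNaseH1 peaks (right); filled coloured points are lists with an adjusted Fisher's exact p under 0.05, open coloured points lists that did not pass, and grey circles the other genes of the same class. For REXO4 the ribosomal RNA genes alone pass, at 73.9% against 1.27%.

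In the REXO4 list, of the same 17 lists, ribosomal RNA genes alone passed. They had a peak at 17 of 23 genes (73.9% against 1.27% of other noncoding genes, odds ratio 219, Fisher's exact adjusted p = 1.67e-26). These were RNA45SN1, RNA45SN2, RNA45SN3, the 18S, 5.8S and 28S genes inside RNA45SN1, and 11 genes of the 5S array on chromosome 1. RNA45SN1 and the genes inside it share 1 REXO4 peak, and the 5S genes are copies in 1 array. The rRNA genes are thus not independent, though the test treats them so for both proteins. The 11 REXO4 peaks at 5S genes had a median fold of 2.16 (1.81 to 2.48), and the 19 RNaseH1 peaks there 7.42. The other 16 lists did not pass, and 8 members outside the rRNA genes had a REXO4 peak. CALM3, a calmodulin gene, had a fold of 2.32 (95% interval 1.90 to 2.80, counting error only), KLF2 1.93 (1.58 to 2.34), DDX5, an RNA helicase, 1.81 (1.43 to 2.27) and SFTPC 2.56 (1.96 to 3.28). These 4 peaks overlapped RNaseH1 peaks, with folds of 2.79, 3.06, 2.74 and 3.76. The peaks at NOP2, an rRNA methyltransferase gene (2.57, 1.81 to 3.55), and WRN, the Werner syndrome helicase gene (2.47, 1.67 to 3.53), did not overlap an RNaseH1 peak, although each gene had a separate RNaseH1 peak at a boundary. SLC17A7 likewise had separate peaks (REXO4 3.41, RNaseH1 3.16), and PTPRN2 had a REXO4 peak only at its boundaries (3.86, 3.44 to 4.32). Ribosomal protein genes had REXO4 peaks at 0 of 78 members against 3.83% of other protein-coding genes (exact adjusted p = 0.654).

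The genes that the transgenes copy were also looked up. REXO4 (chromosome 9, 133406058 to 133418172) and RNASEH1 (chromosome 2, 3531813 to 3558333) had 0 REXO4 peaks each. Each had 2 RNaseH1 peaks, the stronger one within 1 kb of an end of the gene, with folds of 5.52 (4.67 to 6.47) at REXO4 and 3.56 (2.99 to 4.20) at RNASEH1.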

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

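The tests in this part were chosen only after the results were seen, except the test of the boundary share in the full lists, which was planned. The REXO4 list differed from the RNaseH1 list in where its peaks lay. Peaks near a gene boundary made up a larger share of it (odds ratio 2.47, Fisher's exact test), as did peaks in rDNA-bearing sequence (17.9), in gene-free stretches of over 3 Mb (115), on alternate or unplaced sequence (1.93) and at the 5S genes (21.8). The share at tRNA genes did not pass (odds ratio 1.36, Fisher's exact adjusted p = 0.285). The lists differ in length. Among the 500 peaks of lowest q in each, 80 REXO4 and 78 RNaseH1 peaks were in rDNA-bearing sequence, 15 and 0 in gene-free stretches, and 41 and 42 off the assembled chromosomes. Among the 500 of highest fold these counts were 36 and 15, 28 and 0, and 39 and 66.

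The 45S genes RNA45SN1, RNA45SN2 and RNA45SN3 stood out in rank within the REXO4 list. Their 9 REXO4 peaks had folds of at least 4.18, at a median percentile of 98.0 in the list. Copies collapsed onto few positions could raise coverage and with it significance. The 5S array on chromosome 1 fits this, with a median −log10 q of 25.3 against 5.28 for the list and an expected pileup of 126 against 36.6. The spacer between RNA45SN3 and RNA45SN1 belongs to the same repeat as the 45S genes. Its 14 REXO4 peaks had a fold of at most 2.87, below the lowest fold in the genes, at a median expected pileup of 263 against 701 in the genes. A REXO4 peak just past RNA45SN2, from 8220141 to 8220700, had a fold of 4.37, however, above the lowest fold in the genes. The spacer tested also had a lower expected pileup than the genes and was chosen after the values were seen. Whether collapsed copies alone account for the high fold of the genes therefore stays open, as does the significance. Differences between ChIP and control libraries in how much rDNA they hold remain open, since the control is not given in the sources used here.

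The excess near gene boundaries depended on which RNaseH1 peaks it was set against. Against the 1460 of lowest q it turned around (odds ratio 0.576), and against the 1460 of highest fold it stayed (2.16), so the order depended on the ranking used. The REXO4 share near a boundary also varied with expected pileup, from 21.2% in the lowest bin to 77.4% in bin 4 of 5. The lists differ in median expected pileup, 36.6 fragments for REXO4 and 7.14 for RNaseH1, and were not matched on it. The cause was not tested. The 39 REXO4 peaks in gene-free stretches were shallow, with a median of 24 fragments against an expected 4.84. No sequence was used here to tell which repeats they lie in.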

How the results depend on the processing

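Of 48 alternatives planned before the data were examined, 33 were run. The other 15, on GC content, soft-masked repeats and all transcript starts, needed sequence or transcripts that were not used here. A further 11 were added after the data were seen. No paired analysis was possible because the values analysed are 1 peak list per protein, although the groups share replicate numbers. For the same reason no replicate could be left out.

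The overlap of REXO4 with RNaseH1 peaks stayed above random positions in every alternative. The higher share of REXO4 peaks near gene boundaries reversed against the 1460 RNaseH1 peaks of lowest q (odds ratio 0.576) and held against the 1460 of highest fold (2.16). The cause was not tested. Within bins of expected pileup, the mean log2 fold of shared REXO4 peaks differed by -0.00271 from that of all peaks of the same bins (permutation p = 0.51). All values within bins are differences from all peaks of the bins, so their size is not comparable with a difference from unshared peaks. For RNaseH1 peaks the small log2 difference changed sign within bins of width and passed the test there (-0.0308, permutation p = 0.014). With its sign kept, it passed the test with medians (0.0283), with summits within 200 bp (0.0407) and within bins of expected pileup (0.0800), but not near gene boundaries alone (permutation p = 0.17).

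Among gene lists that did not pass, some moved to the other side of their background. For RNaseH1 these were fragile site genes (65% at 500 bp, 95% over gene bodies) and osteoblast genes (75% at 2500 bp). For REXO4 they were R-loop-poor loci (25% over gene bodies), immediate early genes (0% at 500 bp, 4.17% at 2500 bp), nucleolar genes (0% at 500 bp, 0% at the strict q) and R-loop processing factors (0% at the strict q, 6.67% over gene bodies). Ribosomal RNA genes alone passed for REXO4 throughout. For RNaseH1, 11 or 12 lists passed in each setting, not always the same ones. Over gene bodies genes of other tissues lost their call (53.1%) and histone genes gained one (73.7%), and at 2500 bp glycolysis genes lost theirs (94.1%).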

Other observations

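All tests in this part were chosen only after the results were seen, except the test on identical tRNA gene copies, which was written before. RNaseH1 peaks lay at 56.4% of 149 snRNA genes but at 10.3% of 1193 snoRNA genes, many of which sit inside introns of host genes, and at 7.78% of 15416 pseudogenes. REXO4 peaks lay at 1 snoRNA gene. RNaseH1 peaks were densest on the gene-rich chromosomes 19 (613 per 10 Mb), 17 (456) and 22 (363), against 115 on chromosome 4. REXO4 peaks were densest on chromosomes 19 (15.3 per 10 Mb), 21 (14.6) and 17 (13.6). On chromosome 21, 48 of the 61 REXO4 peaks lay within 45 kb of the 45S genes.

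High background coverage may put peaks of both proteins at the same places, since it makes weak enrichment easier to call. In the REXO4 peaks of lowest expected pileup, 16.4% still overlapped an RNaseH1 peak, against at most 6.16% of random positions of the same annotation class (upper end of the 95% range). The random positions were not matched on coverage, and the peak lists hold no coverage outside peaks, so this does not exclude background coverage. For the 3 bins of highest expected pileup, where 94.98% overlapped, it stays open for the same reason. Shared open chromatin is another candidate explanation. A map of RNA:DNA hybrids, which would tell R-loop binding from both, was not used here.

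The tRNA genes at the top of the RNaseH1 list by fold could come from background of the beads, which tends to fall on highly transcribed genes. Such background should then appear in both lines. Of the 345 tRNA genes with an RNaseH1 peak, 20 had a REXO4 peak (5.797%, 95% exact interval 3.58 to 8.81), and of protein-coding genes 3.82% had one. The interval includes that share. Of all 429 tRNA genes 4.66% had a REXO4 peak, against 1.28% of other noncoding genes (odds ratio 3.76, Fisher's exact adjusted p = 2.97e-06), which goes with shared background. As 19 of the 20 lie in a single cluster on chromosome 1, these counts are not independent, and shared background stays open. None of the 186 with an RNaseH1 fold of 10 or more had one, but that threshold was chosen after the folds were seen and excludes nothing. Background in the RNaseH1 line only stays open too, as peaks without doxycycline were not analysed here. Reads shared between identical copies could also raise folds. The 142 tRNA genes with a peak and no identical copy in the annotation had a median percentile of 99.7 in the list. Some of them share their peak with a gene that has copies, such as TRA-TGC4-1 with TRD-GTC2-10 (38.7). Copies were told by gene name, so genes of near-identical sequence were not set apart. The test therefore cannot exclude that shared reads raise the rank of these genes. Genes with identical copies had a peak more often, 90.5% (95% exact interval 85.9 to 94.0) against 71.4% (64.5 to 77.5), so shared reads may add to the number of tRNA genes with a peak.

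RNA polymerase III might set the RNaseH1 fold at small RNA genes. In the fixed list, RN7SL2 (23.4), RN7SL1 (17.1), RN7SK (15.1), RNU6-2 (12.2) and RMRP (10.5) were high. The polymerase II gene RNU4-2 had 11.9, and the polymerase III genes RNU6ATAC (3.14) and RPPH1 (3.51) were low. Medians were 7.22 for 10 peaks at 11 polymerase III genes and 4.06 for 23 peaks at 24 polymerase II genes (exact rank-sum p = 0.144), so the list cannot tell.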
